A study of Mus musculus with 3 samples.

How the data were processed

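CD45+ cells of B16F10 tumours were measured with the 10x Genomics 3' kit, version 3.1, at days 3, 7 and 14 after transfer of Pmel-1 T cells, with equal numbers of cells from 3 mice pooled into each library, per the labels' protocols. The labels differ on how CD45+ cells were taken: the sample protocol names a cell sorter and the series design magnetic beads, and which was used is not settled here. The cell type field of the labels holds a mouse strain, so cell types were rebuilt from the cells. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 4.0.0 on mm10, per the submitters' processing notes. The annotation release and any removal of doublets before deposit are not given in the sources used here. The lowest barcode totals were 500, 501 and 500 UMIs, and median totals were 7388.5, 7929.5 and 8240.

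The groups are the days in the sample titles, with 1 library each. Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, which removed 146, 53 and 117 barcodes. Doublets were scored in each library against simulated doublets. The automatic threshold marked 5, 4 and 1 cells, too few to have worked, so after seeing this the cells with the highest scores were removed at 0.8% per 1000 cells, which took 99, 71 and 94 (2.82%, 2.38% and 2.74%). Counts were scaled to 10000 per cell, log transformed, and reduced to 2000 variable genes and 30 components. The cells were joined by 15 neighbours and clustered with Leiden at resolution 1, and T and NK cells were clustered again.

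Clusters were named from markers chosen in advance, and called by the class whose markers led. The naming rules were revised after the clusters had been seen: a cluster stayed unnamed where over 50% of its barcodes were shared between libraries or Xist-positive and its depth was under 1/3 of the sample's median, or where T cells carried over 1000 CPM of Lyz2; the gamma-delta name needed more Trdc than Trac, and the co-receptor with more UMIs decided between CD8 and CD4. These rules keep 4 clusters out of every class, the unnamed shares of 19.8%, 11.3% and 15.5%. Cluster T5 was CD4 T-like by these rules, but none of the markers of that class was among its 10 leading genes, so it is named by number. Monocyte-like and macrophage-like clusters were pooled into 1 class, as planned, since these cells form a continuum.

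UMIs were summed over the cells of a class in each library and divided by their total (CPM). The sums were 7513854, 8954705 and 7777505 UMIs in CD8 T-like cells and 15691913, 10513295 and 16900505 in monocyte/macrophage-like cells. Sums have exact Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact conditional intervals, all at 95% and all for counting error only. There is no test across mice and no p-value. A gene at 0 in one library was set to a floor of 3 counts. A list member was measured with at least 20 UMIs over the libraries compared, and counted as higher or lower where its ratio was at least 1.5-fold with an interval excluding 1, a rule of size and not a call of change. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

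The 18 lists are effector and cytotoxic, exhaustion and inhibitory receptor, naive and memory, and tissue residence genes of T cells, cell cycle, type I interferon response, interferon-gamma response, MHC class I, MHC class II, alternative activation, inflammatory cytokine, chemokine, hypoxia and glycolysis, lipid handling and lysosome, complement, dissociation and stress, melanoma and erythroid genes. Genes named in the text are, in each class and comparison, the 6 highest and 6 lowest by the interval bound nearest 0 among genes with at least 100 UMIs (without mitochondrial, ribosomal, receptor segment and predicted genes and melanoma or erythroid markers), up to 4 members per list, and 13 genes chosen beforehand. The comparisons, lists, markers, this rule and most alternatives were chosen before the data were examined. The subset of list medians treated as main was chosen later, before the values of the lists were seen. Genes were matched by ID to GENCODE M21 on the same build, 32158 of 32285 (99.6%), only for coordinates.

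Alternatives were other clustering resolutions (0.5 and 2), no cell filter, a stricter filter (500 genes, 5%), doublets kept, gates per cell, TMM scaling, CPM outside mitochondrial and ribosomal genes, the mean over cells of per-cell CPM, and 100 UMIs for list members. Removing shared and Xist-positive barcodes, and the cell with the most UMIs of a gene in each library, were chosen after seeing the data, as were the list medians inside clusters and without T1. TMM factors came from edgeR on the counts. With simulated counts, 95.3 to 95.8% of true ratios lay within their intervals over the 4 comparisons of 8303, 8289, 8609 and 8790 genes. The simulated sums were Poisson draws, the error these intervals assume, so this checks the code only. UMIs gathered in single cells, as in the real data, were not simulated, so the recovery below need not hold for such genes. In CD8 T-like cells a 2-fold difference was recovered for 100% (day 7 over day 3) and 97% (day 14 over day 7) of genes and a 1.5-fold one for 93% and 89%. In monocyte/macrophage-like cells the shares were 100% and 100%, and 97% and 94%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.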

Results

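The data are 3 single-cell RNA libraries of CD45+ immune cells from B16F10 tumours, a mouse melanoma line grown under the skin of C57BL/6 mice. On day 9 after inoculation the mice received Pmel-1 cytotoxic T cells, CD8 T cells whose receptor recognises the melanocyte protein gp100. Tumours were taken on days 3, 7 and 14 after that transfer, and each library pools cells of 3 mice. There is 1 library per day, so no difference between days has a replicate check. No mice without transfer were analysed here, and the day after transfer cannot be told apart from tumour age or from the library. The deposited counts hold 3656, 3038 and 3549 barcodes at days 3, 7 and 14, with 33096709, 29547433 and 35742070 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). After filters, 3411, 2914 and 3338 cells were kept. All intervals below are 95% intervals that cover counting error only.

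The comparison of the days asks how the immune cells of the tumour, and the CD8 T cells among them, differed as time passed after transfer. Monocyte/macrophage-like cells were the largest class at every day, with 40.4% of kept cells at day 3 (38.7 to 42.0), 33.7% at day 7 (32.0 to 35.5) and 39.1% at day 14 (37.5 to 40.8). By the names of its clusters this class held 29.5%, 18.5% and 15.2% monocyte-like cells and 10.9%, 15.2% and 23.9% macrophage-like cells of all kept cells, a division whose marker genes differ by day. Cluster M2, with 16.0%, 5.28% and 6.29% of kept cells at days 3, 7 and 14, was named monocyte-like on a near tie. Its score was 1.33 for monocytes and 1.2 for macrophages, so how these shares differ between days rests in part on that name. CD8 T-like cells made up 14.2% at day 3 (13.0 to 15.4), 20.5% at day 7 (19.1 to 22.0) and 15.7% at day 14 (14.5 to 17.0). NK-like cells, innate lymphocytes that kill without a T cell receptor, made up 7.59%, 16.2% and 5.69%. Their share was higher by 2.13-fold at day 7 than at day 3 (1.84 to 2.46) and lower by 2.84-fold at day 14 than at day 7 (2.42 to 3.34). Treg-like cells, named for the regulator Foxp3, made up 0.91%, 1.65% and 2.19%, and the day 14 share was 2.41-fold that of day 3 (1.59 to 3.65).

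The CD8 T-like share was higher by 1.45-fold at day 7 than at day 3 (1.30 to 1.61) and lower by 1.30-fold at day 14 than at day 7 (1.17 to 1.45). The log2 ratio of day 14 over day 3 was 0.15 (-0.02 to 0.31), a difference not detectable at this depth. Neutrophil-like cells held 5.36%, 5.94% and 5.51%, and conventional dendritic cell-like cells 5.39%, 5.35% and 6.20%, with intervals of every ratio that include no difference. The latter pool cDC1-like and cDC2-like cells. Taken apart, the cDC2-like share at day 14 was 1.35-fold that of day 3 (1.06 to 1.72), and the cDC1-like share 0.84-fold (0.60 to 1.18). Migratory dendritic cell-like cells held 1.47%, 0.89% and 2.01%, plasmacytoid dendritic cell-like cells 1.41%, 0.55% and 1.20%, and B-like cells 2.29%, 0.27% and 1.44%, the last from 78, 8 and 48 cells. Cluster T5, led by Rora, Icos and Bcl11b, scored highest for CD4 T cells, but none of the markers of that class was among its 10 leading genes, so it has no name here. A leading gene had to be detected in at least 50% of cells, and Cd4 was detected in 49.8% of T5 cells, at 182 CPM. It held 1.20%, 3.67% and 5.42%. In place of clusters, a gate on Cd8 and Cd3 UMIs per cell gave a log2 ratio of 0.29 for the CD8 share at day 7 over day 3, against 0.53 by cluster. Requiring 500 genes and under 5% mitochondrial UMIs turned the neutrophil ratio for that comparison to -0.20, from 0.15.

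**Figure D1:**
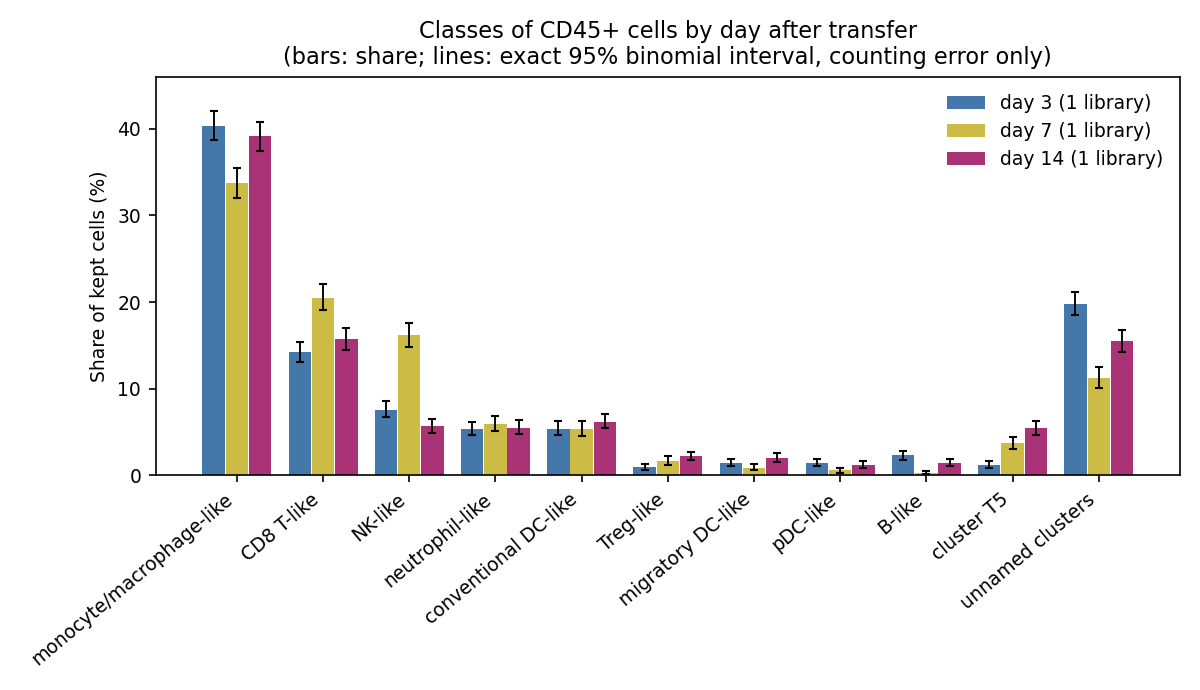
Share of kept cells (%) in each class and in the unnamed clusters at days 3, 7 and 14 after transfer, 1 library each, with exact 95% binomial intervals that cover counting error only. The NK-like share was 16.2% at day 7 against 7.59% at day 3 and 5.69% at day 14.

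Clusters that stayed without a name held 19.8%, 11.3% and 15.5% of kept cells, and their cells had median UMI counts of 676, 706 and 664. They lower the share of every named class in the library that holds most of them. Many of their barcodes occurred in more than 1 library: of barcodes with under 1000 UMIs, 60.9% at day 3, 78.4% at day 7 and 74.3% at day 14 were also found at another day. Of barcodes with 5000 UMIs or more and under 10000, 0.2%, 0.1% and 0.2% were. Shared barcodes under 1500 UMIs also entered named classes, as 1.49% of CD8 T-like, 0.08% of monocyte/macrophage-like, 7.24% of Treg-like, 36.9% of cDC1-like and 1.36% of cDC2-like (the conventional dendritic cell-like classes), 23.1% of migratory dendritic cell-like and 18.3% of plasmacytoid dendritic cell-like cells over the 3 days. Among barcodes of 20000 UMIs or more the shares were 28.9%, 53.7% and 12.5%.

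**Figure D2:**
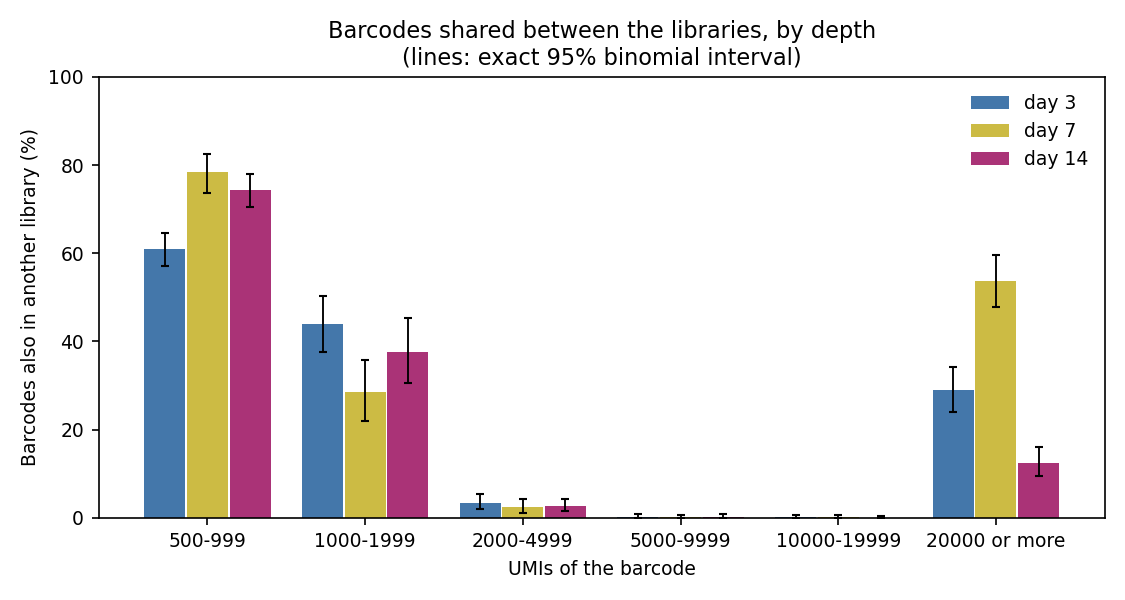
Percent of each library's barcodes that also occur in another of the 3 libraries, by the barcode's UMIs, with exact 95% binomial intervals. Sharing is common below 2000 UMIs and at 20000 UMIs or more, and at most 0.2% between 5000 and 20000 UMIs.

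The transferred cells carry a receptor whose beta chain uses the segment Trbv14, so its share of all Trbv UMIs follows that receptor among CD8 T-like cells. Trbv14 held 65.7% of the Trbv UMIs at day 3 (92 of 140, 57.2 to 73.5), 81.5% at day 7 (277 of 340, 76.9 to 85.5) and 85.3% at day 14 (262 of 307, 80.9 to 89.1). The other segments with the most UMIs at day 3 were Trbv12-2, at 10.7%, and Trbv19, at 6.43%. Treg-like cells, which the transfer should not hold, had 0 Trbv14 UMIs at each day, but only 1, 2 and 2 Trbv UMIs in all. Cluster T5 had 1 of 2, 37 of 49 and 9 of 19. Within the class the share was uneven: T1 had 2 of 14 at day 3, and T7 had 6 of 22 at day 7. Host T cells can also use this segment, and the UMIs come from a minority of the cells, so these shares do not count transferred cells.

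Between day 3 and day 7, RNA of several killing genes in CD8 T-like cells was lower. This comparison asks how the CD8 T-like cells of the tumour differed in the first days after transfer. Some granzymes and interferon-gamma were lower at day 7, and some genes of memory-like cells were higher in the summed RNA. Gzmb, a granzyme that cytotoxic cells inject into their targets, was at 2182 CPM (UMIs of the gene, with the UMIs of the class scaled to a common total) at day 3 and 905 CPM at day 7, lower by 2.41-fold (2.35 to 2.48). Gzma and Gzme, further granzymes, were lower by 3.01-fold (2.86 to 3.17) and 4.10-fold (3.21 to 5.29), and Ifng, the cytokine interferon-gamma, by 3.06-fold (2.91 to 3.21), from 799 to 261 CPM. Gzmc and Gzmf, granzymes as well, were not lower, at 336 and 337 CPM and at 71.7 and 77.8 CPM. A single day 3 cell held 2166 of that day's 6001 Ifng UMIs, and without the top cell of each day Ifng was lower by 2.10-fold. Gzme was found in 13 cells at day 3 and 9 at day 7, and 1 cell held 149 of its 289 UMIs at day 3. Of the 20 effector and cytotoxic genes, 8 were at least 1.5-fold lower with an interval excluding 1 and 2 were as much higher, Ccl5, a chemokine that draws T cells, and Cx3cr1, a chemokine receptor of effector cells. The list's median log2 ratio was -0.37, at percentile 0.03 of 10000 random lists of like expression. Inside the 3 largest clusters of the class it was -0.14 in T1, -0.01 in T4 and -0.06 in T6, each nearer 0 than in the class.

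Other groups in the same cells differed in several directions. Of the 14 genes of naive and memory T cells 6 were higher and 1 lower, with a median of 0.53. Ccr7, a receptor for entry into lymph nodes, was higher by 1.71-fold (1.58 to 1.86), Il7r, the receptor of the survival cytokine IL-7, by 1.62-fold (1.45 to 1.80), and Tcf7, a transcription factor of memory-like T cells, by 1.49-fold (1.35 to 1.66). That direction turns when every cell weighs alike: the median was then -0.14 and the Tcf7 log2 ratio -0.16. The list median was 1.60 (0.67 to 1.85) inside T4 but -0.16 in T1 and -0.57 (-1.62 to -0.19) in T6. Of the 20 exhaustion and inhibitory receptor genes 4 were higher, among them Cd160 by 1.64-fold (1.51 to 1.77), and Tnfrsf9, a costimulatory receptor, was lower by 2.08-fold (1.98 to 2.20), with a list median of 0.02. Pdcd1, the receptor PD-1, was at 174 and 168 CPM (log2 ratio -0.06, -0.16 to 0.05), not distinguishable at this depth. Havcr2, the inhibitory receptor TIM-3, was lower by 1.29-fold (1.12 to 1.48). None of the 22 cell cycle genes passed the size rule (median -0.19), and Mki67, a proliferation marker, was at 151 and 171 CPM. Interferon-gamma response genes had a median of -0.40, with 5 of 18 lower and none higher, and hypoxia and glycolysis genes -0.43, with 5 of 16 lower, among them Bnip3, a mitophagy gene, by 2.01-fold (1.64 to 2.47). Chemokines had a median of -0.58, with 6 of 12 lower: Ccl2, Ccl6, Ccl7, Cxcl9, Cxcl10 and Xcl1. Of Cxcl9 and Ccl6 no cell held over 3 UMIs at day 3, and whether RNA of other cells plays a part was not tested. Dissociation and stress genes had a median of -0.34 (3 of 16 lower, Hsp90aa1, a chaperone, by 1.82-fold), type I interferon response genes -0.22, MHC class I genes -0.17 and tissue residence genes 0.04.

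Ranked by the interval bound nearest 0 among genes with at least 100 UMIs, the genes highest in CD8 T-like cells at day 7 over day 3 were Ifitm1 and Ifitm2, antiviral membrane proteins, higher by 4.6-fold (3.8 to 5.62) and 2.89-fold (2.40 to 3.50), Anxa1, a phospholipid-binding protein, by 4.48-fold (3.07 to 6.70), Dapl1 by 3.04-fold (2.51 to 3.71), Ccl1, a chemokine, by 2.79-fold (2.55 to 3.06), and Nrgn, a calmodulin-binding protein, by 2.72-fold (2.53 to 2.93). Among the lowest by that ranking were Tctex1d2 by 4.13-fold (2.87 to 6.05), Gldc, a glycine-cleaving enzyme, by 3.51-fold (2.86 to 4.33), and Slc7a5, an amino acid transporter of activated T cells, by 3.49-fold (2.92 to 4.19). Ccl1 was found in 35 cells at day 3 and 50 at day 7, and 1 cell held 764 of its 2071 UMIs at day 7. Anxa1 and Ifitm2 were at 146 and 1155 CPM in monocyte/macrophage-like cells at day 3, against 4.39 and 19.7 CPM in CD8 T-like cells. Some genes typical of myeloid cells were at low levels in CD8 T-like cells, such as Cxcl9. It was at 8.78 and 1.23 CPM in CD8 T-like cells, and at 2231 and 509 CPM in monocyte/macrophage-like cells. The medians of lists made mostly for myeloid cells were -0.10 for MHC class II, 0.10 for alternative activation, -0.46 for inflammatory cytokines, 0.05 for lipid handling and lysosome and -0.66 for complement (4 of 12 genes measured). Cluster T4, led by Cd8a, Nrgn and cycling genes, held 57.3% of the class's UMIs at day 3 and 45.6% at day 7, and T9, with 1.86% and 10.9% of its cells, and T11, led by Ifng, at 9.5% and 2.51%, differed most. There is no test of these differences.

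Between day 7 and day 14, RNA of several granzymes, inhibitory receptors and type I interferon response genes in CD8 T-like cells was lower. This comparison asks how the same class differed between the middle and the last time point. Of the naive and memory genes, Klf2 and Id3 were higher at day 14 by the size rule. Gzmb was at 905 and 662 CPM, lower by 1.37-fold (1.32 to 1.42), and Gzmf and Gzmc were lower by 4.32-fold (3.60 to 5.22) and 3.13-fold (2.90 to 3.38). Gzmf was found in only 26 cells at day 7 and 8 at day 14. In each library 1 cell held many of its UMIs, 222 of 697 at day 7 and 77 of 140 at day 14. Of the 20 effector genes 8 were lower and 0 higher (median -0.46), and of the 20 exhaustion genes 7 were lower and 0 higher (median -0.32), among them Lag3, an inhibitory receptor, by 2.04-fold (1.84 to 2.26), and Entpd1, the enzyme CD39, by 2.73-fold (2.05 to 3.67). Inside T1, T4 and T6 the effector median was 0.03, -0.53 and 0.12, and the exhaustion median -0.70, -0.26 and -0.55. Havcr2 was lower by 1.77-fold (1.49 to 2.12), and Pdcd1 was at 168 and 149 CPM. Of 13 measured type I interferon response genes 6 were lower and 0 higher (median -0.57), among them Isg15, a ubiquitin-like antiviral protein, by 2.61-fold (2.14 to 3.19), and Ifit1 by 2.79-fold (1.97 to 4.02). Cluster T6, led by Cd8b1, held 57.6% of the Ifit1 UMIs, 33.9% of the Isg15 UMIs and 52.6% of the Ifitm1 UMIs of the class over the 3 days, and 11.9% of all its UMIs at day 7 against 4.77% at day 14. The type I interferon median inside T1, T4 and T6 was -0.57 (-0.92 to 0.05), -0.68 (-4.47 to 0.10) and -0.19 (-0.68 to 0.66).

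Other groups in the same cells differed less or in other directions. Naive and memory genes had a median of 0.20 and 2 of 14 higher, Klf2, a quiescence factor, by 1.98-fold (1.85 to 2.11), and Id3, a regulator of memory cells, by 1.74-fold (1.45 to 2.10). Tcf7 was at 111 and 162 CPM, higher by 1.45-fold (1.34 to 1.58). Cell cycle genes had a median of 0.11, with none of 22 past the size rule. The median was -0.01 with every cell weighing alike. Ifng was at 261 and 288 CPM, a log2 ratio of 0.14 (0.06 to 0.23), and 0.02 without the top cell of each day and -0.16 with every cell weighing alike. Interferon-gamma response genes had a median of -0.30 (3 of 18 lower), MHC class I genes -0.19, and tissue residence genes -0.22, with Cxcr6, a receptor of resident T cells, lower by 2.34-fold (2.17 to 2.53), and Cd69, an activation marker, higher by 1.53-fold (1.43 to 1.64). Stress genes had a median of 0.25, with Jun, an immediate early gene, higher by 2.23-fold (2.05 to 2.42). Hypoxia and glycolysis genes had a median of 0.09. Day 14 over day 3 gave medians of -0.75 for effector genes, 0.70 for naive and memory genes, -0.77 for type I interferon response genes and -0.60 for interferon-gamma response genes. Inside T1, T4 and T6 the effector median over those days was -0.11, -0.69 and 0.20. The naive and memory median there was -0.15, 1.59 and -0.44, and the type I interferon median -1.12, -0.92 and -0.68.

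MHC class II RNA in CD8 T-like cells was higher at day 14. H2-Eb1, a chain of the class II molecule, was at 12.4 and 37.9 CPM, higher by 3.06-fold (2.45 to 3.84), and Cd74, its invariant chain, at 72.1 and 170 CPM, by 2.36-fold (2.14 to 2.59). The list had 5 of 9 genes higher and a median of 0.72. Monocyte/macrophage-like cells held 1576 and 1681 CPM of H2-Eb1, so the T cell level was low beside theirs. Other myeloid genes were also higher in CD8 T-like cells: C1qa, a complement chain, was at 1.005 and 4.629 CPM, against 323 and 759 CPM in monocyte/macrophage-like cells. These are 9 and 36 C1qa UMIs, and 1 cell held 10 of those at day 14. The complement median was 1.27 (0.49 to 2.2), over only 4 measured genes of 12. The medians were 0.26 for alternative activation, 0.42 for inflammatory cytokines, 0.74 for chemokines, with 6 of 15 higher and 4 lower, and -0.11 for lipid handling and lysosome. Among genes with at least 100 UMIs the highest by interval bound, Jchain and Mzb1, genes of antibody-secreting cells, rest on 1 cell at day 14, with 620 of that day's 623 Jchain UMIs and all 153 Mzb1 UMIs. Trib1, a pseudokinase, and Bmyc were higher by 3.00-fold (2.25 to 4.02) and 2.79-fold (2.22 to 3.52). Serpinb9b, a serpin, Areg, a growth factor, Il10, a suppressive cytokine, and Ifitm1 were lower by 17.4-fold (9.25 to 36.8), 8.88-fold (5.46 to 15.3), 6.69-fold (4.18 to 11.3) and 4.84-fold (3.99 to 5.92). Serpinb9b was at 22.3 and 1.29 CPM. It was found in 27 cells at day 7 and 6 at day 14, Areg in 37 and 8, and Il10 in 26 and 9. T1, led by Tcf7 and Lef1, held 67.0% of the Klf2 UMIs of the class over the 3 days, and 25.9% of its cells at day 7 and 39.2% at day 14. Its CD8 name is the least certain of the class: by its score CD4 T cells came next at 0.11 against 0.17, and Cd8a was at 188 CPM against 569 in the other clusters of the class, although Cd4 was at 4.4 CPM in both and at 182 CPM in T5. Without T1 the naive and memory median was 0.98 at day 7 over day 3 and 0.12 at day 14 over day 7. T7, led by Cd8b1 and Cxcr6 and with Pdcd1, Gzmk, Tox and Rgs16 among its further leading genes, held 19.1% and 9.33% of the class. List medians were not taken inside T7.

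**Figure D3:**
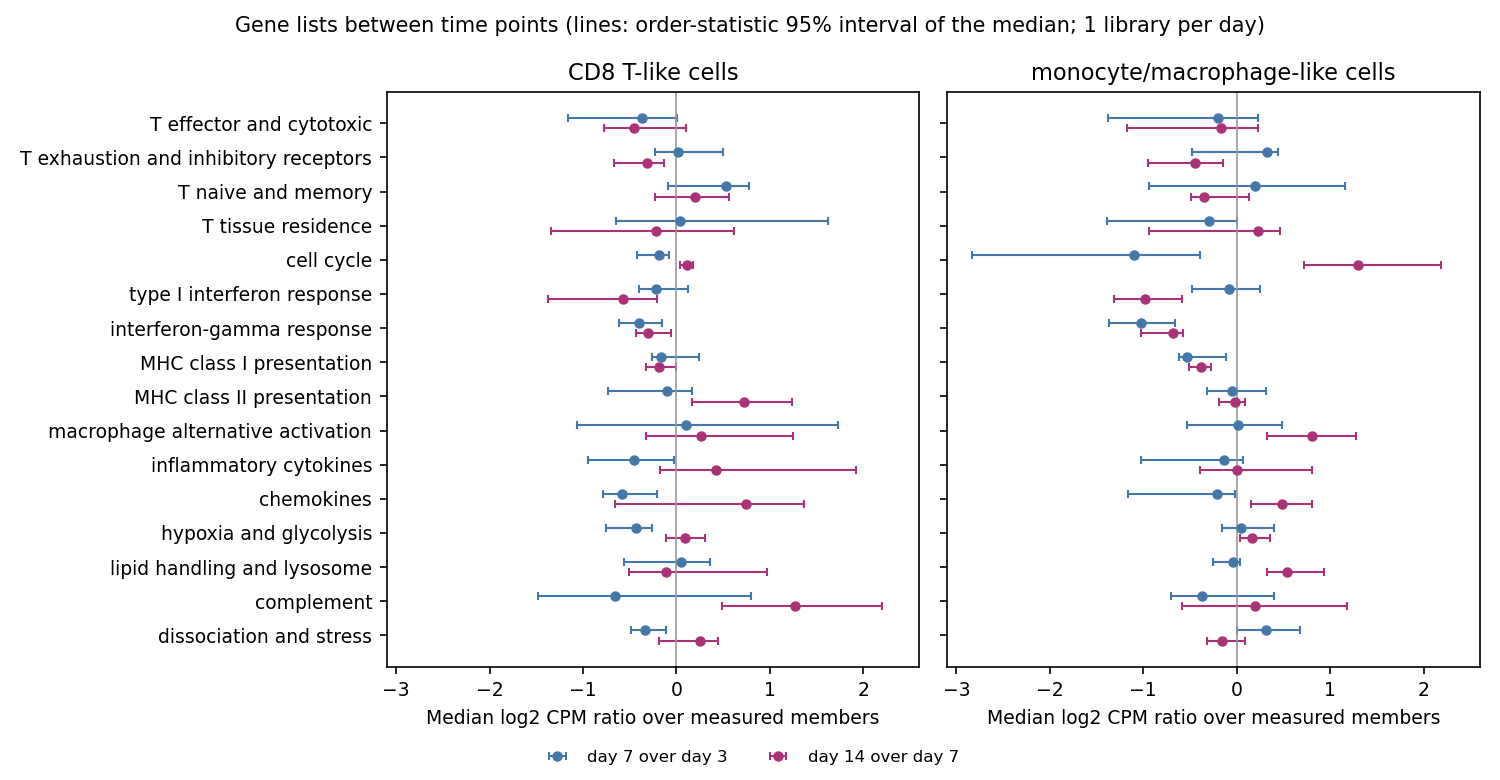
Median log2 CPM ratio over the measured members of each gene list, in CD8 T-like cells (left) and monocyte/macrophage-like cells (right), for day 7 over day 3 and day 14 over day 7, with the order-statistic 95% interval of the median over genes. The interferon-gamma response list in monocyte/macrophage-like cells lies at -1.02 and -0.68.

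In monocyte/macrophage-like cells, interferon-gamma response genes were lower at day 7 than at day 3. This comparison asks how the myeloid cells around the T cells differed as time passed after transfer. Interferon-gamma is made by T and NK cells and induces these genes in macrophages. Cxcl9, a chemokine induced by interferon-gamma, was at 2231 and 509 CPM, lower by 4.38-fold (4.26 to 4.51), and Gbp2, a guanylate-binding protein of host defence, at 2754 and 816 CPM, lower by 3.38-fold (3.30 to 3.46). Of 21 measured list members 16 were lower and 0 higher, with a median of -1.02, at percentile 0 of 10000 random lists. Inside clusters M0, M1 and M2 the median was -0.59 (-1.08 to -0.15), -0.86 and -0.87, each nearer 0 than in the class. M2 held 68.0% of the Cxcl9 UMIs and 55.4% of the Gbp2 UMIs of the class over the 3 days. Its share of the class's cells was 39.7% at day 3 and 15.7% at day 7. Nos2, the nitric oxide synthase of activated macrophages, was lower by 2.02-fold (1.84 to 2.23). MHC class I genes, which share Tap1, Psmb8 and Psmb9 with that list, had a median of -0.53 and 3 of 12 lower, among them Tap2, a peptide transporter, by 1.83-fold (1.71 to 1.96). The MHC class I median was -0.03 (-0.09 to -0.01) inside M0, -0.52 in M1 and -0.34 in M2. Type I interferon response genes had a median of -0.08, with 0.41 (0.09 to 0.62) inside cluster M0, -0.11 in M1 and -0.44 (-0.78 to -0.23) in M2, and MHC class II genes -0.05, with H2-Ab1 at 1816 and 2245 CPM.

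Among the other groups in these cells, Tnf, an inflammatory cytokine, was lower by 2.61-fold (2.44 to 2.79), while Il1b, another, was at 4316 and 4297 CPM, and the inflammatory list had a median of -0.14 with 5 of 13 lower. Chemokines had a median of -0.21 (6 of 19 lower, 0 higher), complement genes -0.37 (3 of 10 lower), with C1qa lower by 1.52-fold (1.46 to 1.58) and Cfb by 2.37-fold (2.23 to 2.51). Alternative activation genes had a median of 0.01: Spp1, a matrix protein of tumour macrophages, was lower by 1.76-fold (1.70 to 1.82), Mmp12, a macrophage elastase, higher by 2.03-fold (1.90 to 2.18), and Arg1, the enzyme arginase, at 748 and 717 CPM, a log2 ratio of -0.06 that was 0.05 with every cell weighing alike. Lipid handling and lysosome genes had a median of -0.04, with Lpl, a lipase, lower by 3.16-fold (3.01 to 3.32), and hypoxia and glycolysis genes 0.05, with Vegfa, a vessel growth factor, higher by 1.62-fold (1.54 to 1.71). Stress genes had a median of 0.31 and 5 of 16 higher, among them Egr1 and Fos, immediate early genes, by 1.78-fold (1.70 to 1.87) and 1.59-fold (1.56 to 1.62). Cell cycle genes had a median of -1.10 and 14 of 22 lower at low levels, such as Birc5 at 11.8 and 1.62 CPM. Cluster M21, led by Pf4 and complement genes, held 6.48% of the class's UMIs at day 3 and 1.15% at day 7.

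Among genes with at least 100 UMIs, those lowest by interval bound were Bcl2l14, Clic5, a chloride channel protein, Edn1, the vasoconstrictor endothelin, Fcrls, a receptor-like protein, Vcam1, an adhesion molecule, and Ch25h, an enzyme making 25-hydroxycholesterol, lower at day 7 by 15.6-fold (8.96 to 29.6), 13.3-fold (8.93 to 20.5), 12.9-fold (8.32 to 21.1), 17.2-fold (8.19 to 43.5), 12.7-fold (8.03 to 21.4) and 9.40-fold (7.25 to 12.4). M21 held 82.7% of the Fcrls UMIs and 52.5% of the Vcam1 UMIs over the 3 days, with 40 cells at day 3 and 11 at day 7, and M2 held 91.5% of those of Bcl2l14, 83.5% of Clic5, 56.5% of Edn1 and 71.1% of Ch25h. Higher were Slco4a1, an organic anion transporter, by 6.09-fold (3.93 to 9.74), G0s2, an inhibitor of fat breakdown, by 4.75-fold (3.58 to 6.38), Pgf, a placental growth factor, by 4.22-fold (3.31 to 5.41), Cd200, an inhibitory ligand, by 3.58-fold (2.68 to 4.82), Ddit4, a stress-induced inhibitor of mTOR, by 3.34-fold (2.71 to 4.13), and Ppp1r3b, a regulator of glycogen, by 2.85-fold (2.38 to 3.44). The G0s2 direction turns with cells gated on Csf1r or Adgre1, to a log2 ratio of -0.13. Erythroid genes had a median of -6.94 that rests on 1 cell at day 3, and melanoma genes 0.34, at 31.3, 33.0 and 34.8 CPM over the 3 days. Mitf alone held 442 of 491, 308 of 347 and 521 of 588 of those melanoma gene UMIs. Of the T cell lists, whose RNA these cells should mostly lack, the medians were -0.20 for effector, 0.32 for exhaustion, 0.20 for naive and memory and -0.30 for residence genes. M2, led by Cfb, Lyz2 and Chil3 and with Gbp2 and Cxcl9 among its further leading genes, held 39.7% of the class at day 3 and 15.7% at day 7. M0, led by Arg1 and Ccl7, held 19.97% and 36.6%, so the class is made of different clusters at the 2 days.

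Between day 7 and day 14, monocyte/macrophage-like cells had more RNA of alternative activation and less of both interferon responses. Genes of lipid handling and the chain C1qa of complement were higher at day 14 in the sum over the class. Spp1 was at 484 and 2439 CPM, higher by 5.04-fold (4.90 to 5.19), and Arg1 at 717 and 1965 CPM, by 2.74-fold (2.67 to 2.81). Of 16 measured alternative activation genes 9 were higher and 0 lower (median 0.81), among them Mmp12 by 2.43-fold (2.31 to 2.56) and Trem2, a lipid receptor, by 2.36-fold (2.15 to 2.58). Within the 3 largest clusters the alternative activation median was 0.26 (-0.10 to 0.99) in M0, 0.08 in M1 and -0.26 in M2, so the value of the class was not seen inside them. M0 held 82.9% of the Spp1 UMIs and 85.0% of the Arg1 UMIs over the 3 days. Its share of the class's UMIs was 41.0% at day 7 and 52.4% at day 14, a smaller rise than those of Spp1 and Arg1. The share of M0 alone therefore does not account for these 2 genes. Of 21 interferon-gamma response genes 15 were lower and 0 higher (median -0.68), among them Socs1, a feedback inhibitor, by 3.47-fold (3.13 to 3.86), and Irf1, a transcription factor, by 2.42-fold (2.30 to 2.55), while Cxcl9 was at 509 and 333 CPM. Of 14 type I interferon response genes 12 were lower and 0 higher (median -0.98), among them Isg15 by 2.07-fold (1.99 to 2.15).

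Lipid handling and lysosome genes were higher for 9 of 18 and lower for 0 (median 0.54), with Lpl higher by 2.41-fold (2.29 to 2.53) and Ctsl, a lysosomal protease, by 2.12-fold (2.04 to 2.20). Inside M0, M1 and M2 the median of that list was 0.39 (-0.18 to 0.63), -0.18 and 0.10. M0 held 74.9% of the Ctsl UMIs over the 3 days, but its share of the class's UMIs, 41.0% and 52.4%, rose less than Ctsl. Chemokines were higher for 7 of 18 and lower for 2 (median 0.48): Ccl8, which draws monocytes, was higher by 3.96-fold (3.63 to 4.33) and Cxcl10, induced by interferons, lower by 2.17-fold (2.12 to 2.23). C1qa was higher by 2.35-fold (2.26 to 2.44), while C3, the central complement protein, was lower by 1.95-fold (1.83 to 2.09), with a complement median of 0.20. Inflammatory cytokines had a median of 0.00, with Cxcl1, a chemokine for neutrophils, higher by 3.41-fold (2.86 to 4.09) and Il1b lower by 1.31-fold (1.29 to 1.33). MHC class I genes had a median of -0.38, and MHC class II genes -0.02, with H2-Ab1 at 2245 and 2260 CPM. Hypoxia and glycolysis genes had a median of 0.16, and Nos2 was at 53.9 and 59.3 CPM, not distinguishable at this depth. Cell cycle genes had a median of 1.30 and 18 of 22 higher at low levels, such as Stmn1 at 7.13 and 26.9 CPM, with cluster M21 holding 1.15% of the class's UMIs at day 7 and 6.45% at day 14. Stress genes had a median of -0.16, effector genes -0.17, exhaustion genes -0.45, naive and memory genes -0.35, residence genes 0.23 and melanoma genes 0.07.

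Among genes with at least 100 UMIs, those highest by interval bound included Fcrls, Vcam1, Gas6, a ligand for uptake of dying cells, Cela1, an elastase, and Igfbp4, a growth factor binding protein, higher at day 14 by 17.3-fold (8.25 to 43.7), 12.0-fold (7.56 to 20.1), 10.2-fold (6.88 to 15.8), 8.61-fold (4.80 to 17.0) and 6.67-fold (4.64 to 9.90). Cluster M21, with 11 cells at day 7 and 49 at day 14, held 82.7% of the Fcrls UMIs of the class, 52.5% of those of Vcam1, 89.5% of Gas6, 69.6% of Cela1 and 70.5% of Igfbp4 over the 3 days. Lower were Slc15a2, a peptide transporter, by 4.70-fold (3.70 to 6.02), Gzma by 4.17-fold (2.74 to 6.48), Lyz1, a lysozyme, by 3.91-fold (3.35 to 4.57), Dmkn by 3.71-fold (3.36 to 4.09) and Egr1 by 3.30-fold (3.11 to 3.49). Gzma was at 7.89 and 1.89 CPM in these cells and at 229 CPM in CD8 T-like cells at day 7. It was also a leading gene of the NK-like clusters T0 and T10, and the NK-like share was 16.2% at day 7 and 5.69% at day 14. Whether RNA of other cells plays a part was not tested. Over day 14 against day 3, all 21 measured interferon-gamma response genes were lower (median -1.92), type I interferon response genes had a median of -1.09, MHC class I genes -0.86 and alternative activation genes 0.62. The alternative activation median over those days was 0.10 in M0, 0.16 in M1 and -0.10 in M2. In the same clusters and order the type I interferon median was -0.40, -1.29 and -0.95, and the MHC class I median -0.44, -0.77 and -0.35, nearer 0 than in the class except type I in M1. M0 held 48.3% of the class at day 14, and M1, led by Chil3 and Lyz2, 34.8% at day 7 and 18.8% at day 14.

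**Figure D4:**
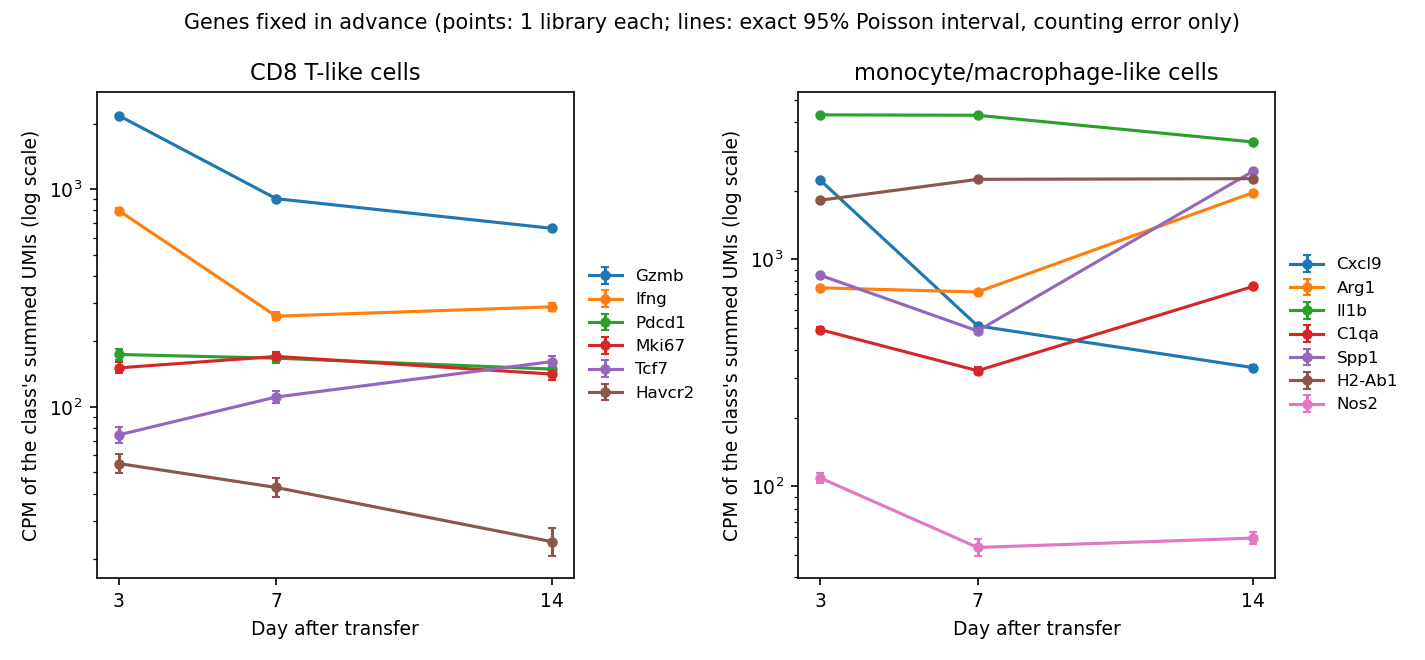
CPM of genes chosen before the data were examined, by day after transfer (log axis), in CD8 T-like cells (left) and monocyte/macrophage-like cells (right), 1 library per point, with exact 95% Poisson intervals. Gzmb lies at 2182, 905 and 662 CPM and Spp1 at 850, 484 and 2439 CPM.

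The genes singled out lie at these places in mm10. Gzmb (ENSMUSG00000015437) spans bases 56258838 to 56262260 of chromosome 14, Ifng (ENSMUSG00000055170) 118441046 to 118445892 of chromosome 10, Tcf7 (ENSMUSG00000000782) 52252371 to 52283014 of chromosome 11, Cxcl9 (ENSMUSG00000029417) 92321347 to 92328079 and Spp1 (ENSMUSG00000029304) 104435118 to 104441050 of chromosome 5, and Arg1 (ENSMUSG00000019987) 24915221 to 24927484 of chromosome 10. Granzymes on chromosome 14, the MHC genes, Lyz1 with Lyz2, Ifitm1 with Ifitm2 and the guanylate-binding proteins are close relatives, and the share of UMIs split or lost between such copies in the authors' counting is unknown.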

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

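Of the tests below, all but those of the pairs of low copies and of the cluster mix were chosen after the result, or values closely related to it, had been seen.

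Barcodes under 1500 UMIs that occur in more than 1 library carried Xist RNA at 632 CPM at day 3, 623 at day 7 and 618 at day 14, against 0.23, 0.33 and 0.09 CPM in barcodes of at least 5000 UMIs. Barcodes under 1500 UMIs that were not shared carried it too, at 462, 0 and 411 CPM. Of 1285 low shared barcodes among the kept cells 1097 lie in the unnamed clusters, and 188 lie in named classes or T5, where they hold 0.163% of the UMIs. Chance reuse of barcodes would give at most 8.06 shared between days 3 and 14, where 533 were found, and free RNA of the same library would not give Xist at a lowest ratio of 1888.8. In 781 pairs of low copies, 99.4% fell on the same side (T or NK cells, or others), against 50.2% for shuffled pairs, which is consistent with copies of cells carried over from a library that was handled or sequenced alongside. A part may come from these libraries' own deepest cells: of 378 pairs of a low and a deep copy 98.9% fell on the same side, against 54.1% shuffled, and the 459 low copies with a deep partner had 6.1 CPM of Xist against 915 CPM in the 798 whose copies were all low. The source of the Xist RNA was not identified here, and no biological explanation was tested.

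Interferon-gamma response genes were lower at later days in monocyte/macrophage-like cells, with a median log2 ratio of -1.92 for day 14 over day 3. Another mix of clusters is argued against as the whole of it, since the median nearest 0 in the 3 largest clusters was -1.37, and a scaling factor common to all genes is argued against, since the median of the list less that of all genes in the class was -1.93. Less interferon-gamma RNA among the CD45+ cells is a candidate explanation. Ifng over all kept cells had a log2 ratio of -1.30 at day 7 over day 3 and -0.19 at day 14 over day 7. Without the top Ifng cell of each day the ratios were -0.90 and -0.28. These sums include the unnamed clusters, which held 13.5%, 2.7% and 9.0% of the Ifng UMIs at days 3, 7 and 14. In summed UMIs, Ifng was not lower at day 14 than at day 7 in its main sources among the named cells and T5. The log2 ratio was 0.14 in CD8 T-like cells, with 120 and 275 CPM in NK-like cells and 53.0 and 105 CPM in T5. In CD8 T-like cells, the largest source, that direction turned with every cell weighing alike. There 289 of 598 cells had an Ifng UMI at day 7 and 231 of 525 at day 14. Whether Ifng per cell was lower at the second step is therefore not settled. The CD8 T-like and NK-like shares of kept cells were 20.5% and 16.2% at day 7 and 15.7% and 5.69% at day 14. With fewer such cells, lower Ifng over all kept cells need not mean lower Ifng per cell. Tumour age, the library and the transfer itself stay open, as they cannot be separated in this design.

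MHC class II genes were higher in CD8 T-like cells at day 14 than at day 7. Without the 5% of cells with the most class II UMIs in each library the log2 ratio of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 together was 0.71 (0.57 to 0.85), against 1.25 (1.15 to 1.36) with all cells, so mixed droplets are not excluded as a part of it. More free RNA at day 14 may add to it, with 1.22 in NK-like cells (2.30 with all cells), but Treg-like cells gave -0.25 (-1.61 with all cells). The explanations cannot be told apart, because a bound set for the first was reached only within counting error and the classes disagree on the second. Expression by the T cells themselves was not tested.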

How the results depend on the processing

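Removing shared and Xist-positive barcodes, and the cell with the most UMIs of a gene in each library, were chosen after seeing the data. With 1 library per day there was no replicate to leave out, and the intervals show counting error alone. Trbv14 shares stayed within their intervals under all 7 alternatives. Class share ratios at day 7 over day 3 moved for CD8 T-like cells with gates per cell (0.29), for monocyte/macrophage-like cells with the stricter filter (-0.44) and without shared barcodes (-0.39), and for neutrophil-like cells with the stricter filter (-0.20). Of 28 main list medians, none moved under 7 alternatives. With the mean over cells, 2 moved at day 7 over day 3 in CD8 T-like cells, naive and memory genes (-0.14, a change of sign from 0.53, whose interval included 0) and type I interferon response genes (-0.42), and cell cycle genes changed sign at day 14 over day 7 (-0.01). Of 304 ratios of named genes, 127 moved and 4 reversed with the mean over cells, and 115 moved and 5 reversed with gates per cell. TMM moved 5 and reversed 0, with factors in monocyte/macrophage-like cells so near 1 (1.0017, 0.9998 and 0.9984) that it tests little there. Reversed with the mean over cells in CD8 T-like cells were Tcf7 at day 7 over day 3 (-0.16) and Tnfaip3 (0.03) and Ifng (-0.16) at day 14 over day 7, and in monocyte/macrophage-like cells Arg1 at day 7 over day 3 (0.05). With gates per cell Cxcl2 (0.89) at day 7 over day 3 and Cxcl3 (-1.28) at day 14 over day 7 reversed in CD8 T-like cells, and G0s2 (-0.13), Cxcr6 (1.39) and Ccl17 (1.71) at day 7 over day 3 in monocyte/macrophage-like cells. Without the top cell Hbb-bs (0.16), Hba-a1 (1.16) and Hba-a2 (1.16) reversed at day 7 over day 3, since 1 cell holds nearly all their UMIs. Apart from that the cause was not tested. Counts of list members past the size rule that differed by over 1.5 times were small ones: in CD8 T-like cells at day 7 over day 3, effector genes higher were 2, 1 with the stricter filter and 0 without shared barcodes, naive and memory genes lower 1 and 0 with the stricter filter, and residence genes lower 1 and 0 outside ribosomal genes; at day 14 over day 7 naive and memory genes higher were 2 and 4 with doublets kept, and complement genes lower in monocyte/macrophage-like cells 2 and 1. The other such counts differed by 1 gene. CPM outside mitochondrial and ribosomal genes shifted the median of all genes by 0.105 in CD8 T-like cells at day 14 over day 3.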

Other observations

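The test of Trbc2 below was chosen after related values had been seen.

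The interferon-gamma response list was also lower at day 7 and again at day 14 in neutrophil-like and cDC2-like cells. In neutrophil-like cells its median log2 ratio was -1.03 at day 7 over day 3 and -1.51 at day 14 over day 7, with Socs1 lower by 11.7-fold in the second, and MHC class I genes had a median of -1.73 at day 14 over day 3. Markers of other myeloid cells differed in this class too, with MHC class II medians of 0.56 and then -2.3, and Gpnmb, a lysosomal protein of macrophages, higher by 4.05-fold and then lower by 2.81-fold. Stress genes had a median of 0.65 at day 7 over day 3. In cDC2-like cells, a conventional dendritic cell class, the interferon-gamma list gave -1.05 and -0.37, with Gbp2 lower by 3.32-fold at day 7 over day 3, and in NK-like cells it gave -0.10 (-0.55 to 0.08), then -0.45. The cDC2-like cells also differed in markers of macrophages: complement genes had medians of -2.0 and then 2.69, with C1qa lower by 4.81-fold and then higher by 9.37-fold, and alternative activation genes -0.37 and then 0.98. Whether other cells mixed into these classes alter their other values was not tested. Cell cycle genes were higher in cDC2-like cells at day 14 over day 7, with a median of 1.53, 18 of 21 members higher and 3 lower. Top2a, a topoisomerase of dividing cells, was higher by 4.43-fold. In NK-like cells that list gave 0.29 and then 0.56, with Stmn1, a tubulin regulator, higher by 2.30-fold and 2.41-fold. At day 14 over day 7 these cells also had medians of 1.38 for MHC class II and 1.61 for inflammatory cytokines, and 7 of 16 stress genes were higher. Whether other cells mixed in alter the NK-like values was not tested. Cluster T10, led by Gzmc, held 21 of 259 NK-like cells at day 3, 59 of 471 at day 7 and 39 of 190 at day 14. Gzmc in NK-like cells was at 828 CPM at day 3 and 1932 at day 7, while Ifng was at 377, 120 and 275 CPM over the 3 days.

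Erythroid RNA came to 4660 UMIs at day 3, 1 at day 7 and 6 at day 14. Only 1 cell at day 3 had at least 10 such UMIs, and the 10 cells with the most held 99.7% of that day's. RNA of the melanoma list came to 18.2, 14.7 and 20.1 CPM over all kept cells. Monocyte/macrophage-like cells held 491 of 550, 347 of 409 and 588 of 663 of these UMIs. There Mitf alone gave 442, 308 and 521, against 13, 14 and 18 for Pmel and 13, 11 and 26 for Dct. The values therefore mostly follow Mitf and do not measure tumour RNA.

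A hypothesis is that Trbc2 RNA in CD8 T-like cells comes in excess from cells with the transferred receptor, which may carry an added receptor gene. Cells with a Trbv14 UMI had more Trbc2 than cells with a UMI of another Trbv segment only, by a lowest ratio of 2.75 over the 3 days (4.66, 3.11 and 2.75), which is consistent with it. Trbc1 was also higher in the first set at day 3, by 2.17-fold, with ratios of 0.96 and 0.80 at the later days, and at day 14 the sets differed in depth, with median UMIs of 25595 and 7491.5. Cells that show a Trbv UMI at all may differ in receptor RNA for other reasons, which were not tested.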
